A study of Homo sapiens with 9 samples.

How the data were processed

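RNA of 9 samples of HEK293, a human embryonic kidney line, was measured on Affymetrix arrays with a single colour, 1 array per sample. The deposited values are linear signal intensity per probe set, with 22283 probe sets in the table and 0 other columns per sample. Neither a header nor a label names the software, the background correction or a detection call, so none is stated here. The deposited intensity values had been scaled before deposit: the mean of the middle values of each array, between the 2nd and the 98th percentile, lay between 499.87 and 499.90 on all 9 arrays. They were therefore used as deposited, with quantile normalization as the alternative.

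All steps from there were computed for the present comparisons. Values were taken as log2(signal + 43), where 43 is the 25th percentile of all values, so that the size of a log2 change depends on this constant where a signal lies near or below it. The 68 Affymetrix control probe sets were kept out of the tests. Probe sets whose mean log2 value over the 9 arrays lay above the 25th percentile of such means were tested, which left 16661. Of the 22283 probe sets, the annotation lists 1 gene for 19071, several genes for 1043 and none for 2169, and 19059 of those with 1 gene were matched to the current gene table by gene ID. For counts of genes and for gene lists, each of 9617 genes was represented by its probe set with the highest mean. Genomic positions were not used.

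The arrays fall into 5 groups by the labels: wild type (2 arrays), transient EGFP vector (2), transient EWS-FLI1 (2), G418-selected EGFP vector (1) and G418-selected EWS-FLI1 (2, a bulk population and clone F). Cells of both transient groups were taken 48 h after transfection. The labels name separate RNA isolations for the wild-type pair and separate transfections for the transient pairs. For the G418-selected cells, whether the bulk population and the clone came from separate transfections is not stated. P-values therefore measure only the spread between these arrays. Array numbers did not pair across groups: the differences between the arrays of a pair correlated across probe sets at 0.016, -0.022 and 0.009.

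One linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend), leaving 4 residual degrees of freedom. The spread of groups with 1 array is assumed to equal that of the others. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the 16661 probe sets, with a threshold of 0.05. The contrasts were EWS-FLI1 against EGFP in transient cells, the same in stable cells, the mean of both, the stable minus the transient effect, and each EGFP group against wild type.

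Before the data were examined, 20 gene lists were fixed from general knowledge: EWS-FLI1 activated targets, EWS-FLI1 repressed targets, neural crest and neural genes, endothelial genes, cell cycle, p53 targets, interferon response, heat shock, unfolded protein and amino acid stress, cholesterol synthesis, glycolysis and hypoxia, extracellular matrix and adhesion, immediate early genes, ETS family factors, ribosomal proteins, mitochondrial respiration, markers of blood cells, of fibroblasts and of keratin-positive epithelial lines, and kidney and adrenal genes. They hold 564 genes, of which 503 have a probe set with 1 gene and 432 were tested. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 20 lists of a comparison, and again with an estimated correlation. Clone F and the bulk population, 1 array each, were compared without a test, by the percentile of a list's median among 10000 random lists matched on mean expression.

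The genes named were also set by a rule fixed before the data were examined. FLI1 and EWSR1 come first, on every array. Then come the 10 genes with the largest positive and the 10 with the largest negative change among genes past the threshold whose groups do not overlap, filled up by the smallest p where fewer passed, and up to 4 members per list with the smallest p. Exceptions are named where they occur.

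The model was tested on simulated arrays with the same design and 16661 probe sets, with 50 changed at each of 4 sizes. At a log2 change of 1, 56% were recovered for the transient comparison, 32% for the stable, 70% for the mean of both and 14% for the difference. At a log2 change of 2 the shares were 88%, 52%, 90% and 38%. For EGFP against wild type, 60% were recovered at a log2 change of 1 in transient and 34% in stable cells, and 86% and 66% at a log2 change of 2. Unchanged probe sets called numbered 10 for the transient comparison, 17 for the stable, 12 for the mean of both and 7 for the difference. For EGFP against wild type they numbered 2 in transient and 9 in stable cells. The simulated noise was normal and independent, and bulk and clone F were given the same change, so real arrays can do worse. The number of arrays limits the precision of each comparison.

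The alternatives were quantile normalization, added constants of 10.75 and 162, no filter, a filter at the 50th percentile, a fit of only the groups compared, wild type or all 5 arrays without EWS-FLI1 as control, a replicate term, the mean of a gene's probe sets, and leaving out each array. Some of the settings were chosen after seeing the data. These were bulk and clone F as separate groups, the list test of the difference and the comparison of the 3 G418-selected arrays with the other 6. The list tests without each array, with wild type as control or with all 5 arrays without EWS-FLI1 as control were also chosen then. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.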

Results

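The series asks what EWS-FLI1 does to gene expression in HEK293 cells. EWS-FLI1 is the fusion transcription factor of Ewing sarcoma, which joins the amino-terminal part of EWSR1 to the DNA-binding domain of FLI1, a member of the ETS family. Expression was measured on 9 arrays: 2 of wild-type cells, 2 of cells transfected transiently with the EGFP vector, 2 transfected transiently with EWS-FLI1, 1 of stable EGFP cells and 2 of stable EWS-FLI1 cells, a bulk population and clone F. Stable cells had been selected with G418, an antibiotic used to select cells that carry a resistance gene. Median signal lay between 129.8 and 186.5, and it was lowest on the stable arrays at 156.1 for EGFP, 141.0 for bulk and 129.8 for clone F. Across the 22215 probe sets other than controls, before the filter, Spearman's correlation was computed between the arrays of a pair. It was 0.938 for wild type, 0.914 for transient EGFP, 0.936 for transient EWS-FLI1 and 0.909 for bulk and clone F. The number of arrays limits the precision of every comparison, and the stable EGFP array has no replicate.

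The introduced gene was read first. FLI1 (probe set 211825_s_at) gave a signal of 4952.1 and 4486.4 on the transient EWS-FLI1 arrays. It gave 12.6 and 112.0 in wild type, 72.3 and 34.5 with transient EGFP, 30.7 in the stable EGFP cells, 379.2 in the EWS-FLI1 bulk population and 150.7 in clone F. The other FLI1 probe sets stayed low: 210786_s_at read 79.9 and 148.6 on the transient EWS-FLI1 arrays against 129.4 and 135.6 with EGFP, and 204236_at read 41.2 at most on any array. EWSR1 (209214_s_at) read 3147 ± 196 (SD, n = 2) with transient EWS-FLI1 and 2552 ± 11.5 (SD, n = 2) with EGFP, a log2 change of 0.30 that missed the threshold (adjusted p = 0.853). Its other probe sets, 210011_s_at and 210012_s_at, differed by 0.27 and 0.09 on the log2 scale without passing.

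**Figure D1:**
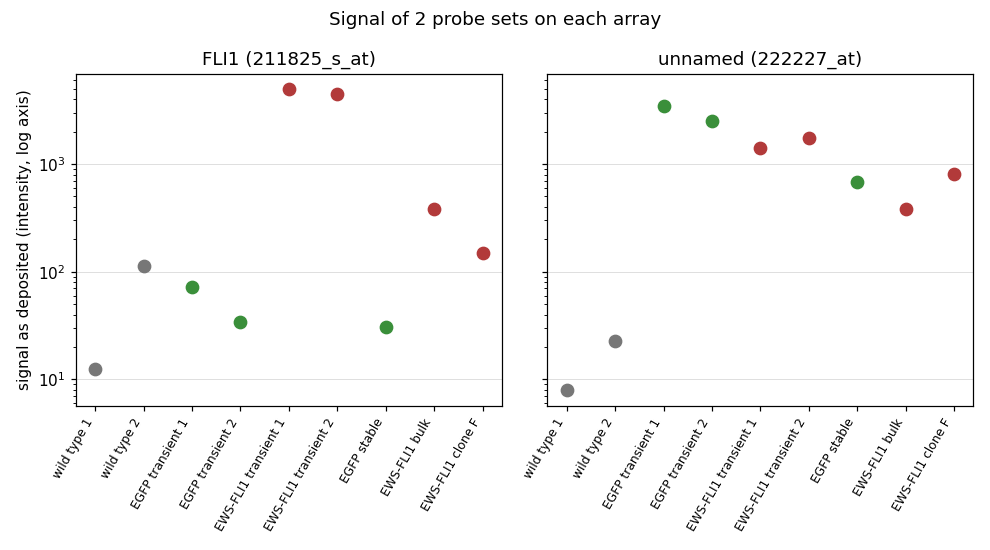
Signal as deposited (intensity, log axis) of FLI1 and of the unnamed probe set 222227_at on each of the 9 arrays; every point is 1 array, grey for wild type, green for EGFP and red for EWS-FLI1. FLI1 reads 4486.4 or more on the transient EWS-FLI1 arrays and 379.2 or less on all others, and 222227_at reads 384.3 or more on the 7 transfected arrays and 22.9 or less in wild type.

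The transient comparison asks what EWS-FLI1 changes within 48 h beyond the vector. FLI1 rose from 53.4 ± 26.7 to 4719 ± 329 (SD, n = 2 each), a log2 change of 5.65 (SE 0.47, adjusted p = 0.000438) whose size depends on the added 43, since 1 of the EGFP values lay below it. As a group, targets of p53, the tumour suppressor that responds to DNA damage, rose: 15 of the 17 members tested were higher, with a median log2 change of 0.38 (camera adjusted p = 2.4e-05; adjusted p = 0.631 with an estimated correlation). Of these 17, 0 passed over all genes and 4 rose when adjusted over the list alone. BAX, which promotes apoptosis, read 903 ± 151 against 323 ± 22.0 with EGFP and 458 ± 110 in wild type (SD, n = 2 each). SESN1, a sestrin induced by stress, changed by 0.81, the repair gene DDB2 by 0.76 and the death receptor FAS by 0.94 on the log2 scale. Against wild type the list rose as well (adjusted p = 1.16e-09).

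The EWS-FLI1 targets known from other cells did not move as groups. Of 39 activated targets tested, 0 passed over all genes and 0 adjusted over the list alone, and 23 were higher (camera adjusted p = 0.680). STEAP1 differed by 0.73, CAV1 by 0.70, VEGFA by 0.55 and TNC by -0.67 on the log2 scale. Of 30 repressed targets, 0 passed in either way and 18 were higher (adjusted p = 0.718), with COL6A2 at 1.00. Among immediate early genes, which respond within minutes to growth signals, IER2 rose when adjusted over the list alone, from 3401 ± 204 to 6073 ± 161 (SD, n = 2 each), while the list missed the threshold (adjusted p = 0.059). For neural crest and neural genes, 9 of 26 were higher (adjusted p = 0.129). The 1 of 19 ETS family factors that rose was FLI1 itself (adjusted p of the list 0.995). No member passed, over all genes or adjusted over the list alone, among ribosomal proteins (adjusted p = 0.575), endothelial genes, unfolded protein and amino acid stress, cholesterol synthesis, glycolysis and hypoxia, extracellular matrix and adhesion, and markers of fibroblasts (0.718 each), markers of keratin-positive epithelial lines (0.883), interferon response (0.977), or cell cycle, heat shock, mitochondrial respiration, markers of blood cells, and kidney and adrenal genes (0.995 each).

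Apart from FLI1, the genes with the smallest p missed the threshold. They were BAX, SLC10A3, TPM2, IER2, NRSN2, ANO10, TRABD, NME4 and PTPN1, with log2 changes from 0.83 to 2.04 and adjusted p from 0.166 to 0.443. Those lower were DHRS2, PDPK1, TIPARP, MLX, BRD2, CA2, PML, SLN, SPP2 and CHRNA3, with log2 changes from -0.60 to -1.70 and adjusted p from 0.188 to 0.615. Other probe sets of TPM2, MLX and PML had the opposite sign. For some of them the EGFP arrays stood apart from wild type and EWS-FLI1 alike: SLC10A3 read 9.0 ± 2.26 with EGFP, 174 ± 36.1 in wild type and 173 ± 43.8 with EWS-FLI1, and DHRS2 read 1358 ± 27.7, 270 ± 130 and 435 ± 11.1 (SD, n = 2 each). In all, limma called 1 of 16661 probe sets up and 0 down, with 1047 at an unadjusted p under 0.05 where chance gives 833. The count was 0 without EWS-FLI1 transient replicate 2 or EGFP transient replicate 2, 2 without EWS-FLI1 transient replicate 1, 28 without the bulk array and 27 without clone F. Bulk and clone F enter this comparison only through the pooled spread. A fit of only the groups compared called 13 up and 7 down, with BAX (adjusted p = 0.00836), IER2 (adjusted p = 0.00871) and SESN1 (adjusted p = 0.0279) among them. After FLI1, the smallest p belonged to DHRS2, PRRC2C, ARHGDIA and EIF4G1, with log2 changes of -1.55, 2.17, 1.30 and 1.15. For these, transient EGFP differed from wild type with the opposite sign, by 2.23, -2.25, -0.89 and -0.91. Their changes thus rest at least in part on the EGFP arrays.

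In stable cells the question is the same after G418 selection, with bulk and clone F set against the single EGFP array. FLI1 was higher by 1.96 on the log2 scale without passing (adjusted p = 0.183). The list of unfolded protein and amino acid stress rose relative to EGFP: 20 of 24 members were higher, with a median log2 change of 0.32 (camera adjusted p = 0.00547; adjusted p = 0.906 with an estimated correlation). Of its members, 0 passed over all genes. Adjusted over the list alone, DDIT3, a transcription factor of endoplasmic reticulum stress, rose by 1.19, and HSP90B1, a chaperone of that compartment, fell by 1.44 on the log2 scale. DDIT3 read 346.8 in bulk and 311.9 in clone F against 120.4 in the EGFP array, but 389 ± 46.4 in wild type (SD, n = 2). Against wild type the list was lower in the stable EWS-FLI1 cells (adjusted p = 0.000135).

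Genes of cell division moved both ways in stable cells. Of 34 cell cycle genes, 0 passed over all genes, and 9 fell and 1 rose adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.714, leaning downward): 20 members were higher and 14 lower, with a median log2 change of 0.04 and a mean of -0.24. The 1 that rose was CDC20, named here after its values were seen, at 4394 ± 242 (SD, n = 2) against 3118.9 with EGFP. TOP2A, the topoisomerase that untangles chromosomes, read 1173 in bulk and 626.2 in clone F against 1948.1 with EGFP. The spindle checkpoint kinases TTK and BUB1 differed by -1.55 and -1.09, and the spindle motor KIF11 by -1.19 on the log2 scale. Heat shock genes HSPH1, HSP90AA1 and HSPA4 fell adjusted over the list alone, as did NEFM (-0.58) among neural genes and CCNG1 (-0.97) among p53 targets. L1CAM fell relative to EGFP adjusted over the list alone (-1.14), but it read 856 ± 93.4 with EWS-FLI1, 1929 on the EGFP array and 589 ± 58.6 in wild type (SD, n = 2 each), so that the EGFP array stood apart. IGFBP5, which binds insulin-like growth factors, rose adjusted over its list of repressed targets alone, at 315.7 in bulk and 2291.2 in clone F against 62.6 with EGFP. None of the 39 activated targets passed, with 0 over all genes and 0 adjusted over the list alone, and ID2 differed by -1.10 on the log2 scale, at 2273 ± 1056 against 4660.1 with EGFP and 2194 ± 158 in wild type (SD, n = 2 each).

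Over all genes, limma called 0 probe sets in stable cells, with a smallest adjusted p of 0.132. At an unadjusted p under 0.05 there were 2328, of which 701 were higher and 1627 lower, where chance gives 833. Lowest by p were TP53BP1, THAP12, METTL5, NUP50, PDCD10, ZFR, DLG1, ATAD2, RAD51AP1 and CA2, with log2 changes from -1.01 to -1.66. TP53BP1, an adaptor of the DNA damage response, read 206 ± 11.5 (SD, n = 2) against 744.4 with EGFP and 651 ± 25.4 (SD, n = 2) in wild type. Those higher were ZSCAN18, GAB2, KIAA0513, ALDH9A1, POM121C, MAGED1, DAPP1, SETMAR, HMX1 and IGFBP5, with log2 changes from 0.80 to 3.12. For ZSCAN18, KIAA0513 and DAPP1 the EGFP array stood apart from wild type and EWS-FLI1 alike, ZSCAN18 reading 122.7 with EGFP, 444 ± 31.3 with EWS-FLI1 and 511 ± 39.2 in wild type (SD, n = 2 each). Other probe sets of NUP50 and IGFBP5 had the opposite sign. Without the bulk array 2136 probe sets passed (551 up, 1585 down) and without clone F 53 (11 up, 42 down), each with the lone array assumed to vary like the other groups. Without clone F the stress list no longer passed (adjusted p = 0.201), and with bulk and clone F as separate groups, a fit chosen after seeing the data, 245 probe sets passed upward and 1080 downward.

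**Figure D2:**
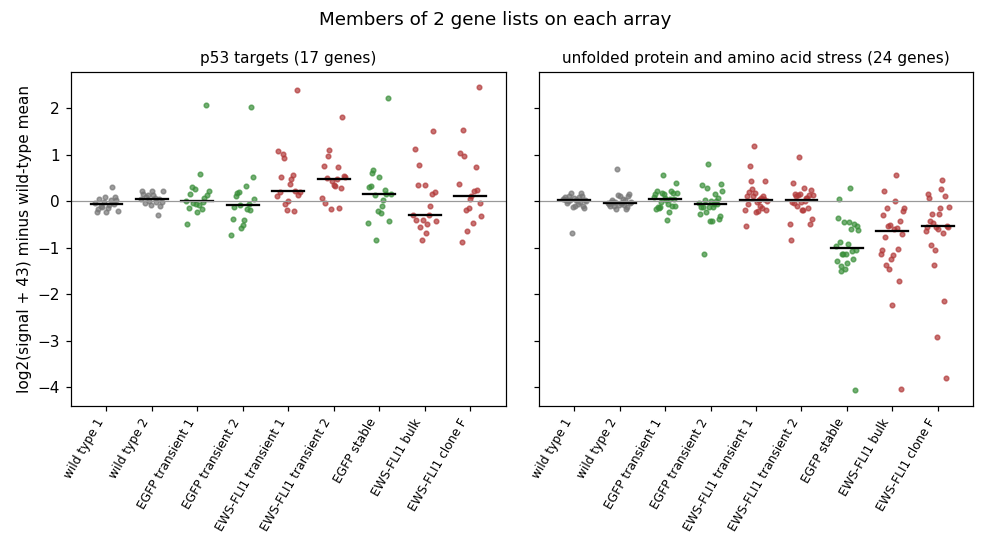
Members of the p53 target list (17 genes) and of the unfolded protein and amino acid stress list (24 genes) on each array, as log2(signal + 43) minus the wild-type mean; each point is 1 gene and each black line the median, with grey for wild type, green for EGFP and red for EWS-FLI1. Median p53 targets lie at 0.21 and 0.47 on the transient EWS-FLI1 arrays and at 0.01 and -0.07 with transient EGFP, and median stress genes lie at -1.01, -0.64 and -0.54 on the stable EGFP, bulk and clone F arrays.

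Taking both modes with equal weight, FLI1 rose by 3.80 (SE 0.37, adjusted p = 0.0028). The only other probe set called was 208624_s_at of EIF4G1, a scaffold of translation initiation, named here after its values were seen. It rose by 1.13 on the log2 scale (SE 0.13, adjusted p = 0.00937), from 956 ± 9.60 on the EGFP arrays (SD, n = 3) to 2181 ± 96.7 with transient and 2095 ± 203 with stable EWS-FLI1 (SD, n = 2 each). Wild-type cells read 1842 ± 134 (SD, n = 2), and the other EIF4G1 probe set, 208625_s_at, did not pass (0.12, adjusted p = 0.763). The list of unfolded protein and amino acid stress rose, with 17 of 24 members higher (adjusted p = 0.0277; adjusted p = 0.662 with an estimated correlation), DDIT3 up and HSP90B1 down adjusted over the list alone and 0 over all genes. That list missed the threshold after quantile normalization (adjusted p = 0.0679), without EGFP transient replicate 2 (0.171), without clone F (0.156) and without EWS-FLI1 transient replicate 1 (0.0741). With all 5 arrays that lack EWS-FLI1 as the control it did not pass either and leaned downward (0.300). In transient cells alone its median log2 change was 0.03, with 13 of 24 members higher (camera adjusted p = 0.718). The median change in stable cells was 0.32, against a single EGFP array. Relative to wild type, that array's median was -1.01, with bulk at -0.64 and clone F at -0.54. Over both modes the p53 targets and the immediate early genes missed the threshold at a camera adjusted p of 0.0534 each, with BAX and IER2 up adjusted over the list alone.

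CA2, a carbonic anhydrase, was the nearest gene below the threshold: it read 5568 ± 46.3 with transient and 5648 ± 1248 with stable EWS-FLI1, against 9034 ± 1019 with transient EGFP (SD, n = 2 each), 11274.3 with stable EGFP and 8843 ± 545 in wild type (SD, n = 2), a log2 change of -0.85 (adjusted p = 0.093). Others that were lower by p were TP53BP1, NUP50, CTNNAL1, ATP13A3, DLG1, LTN1, BTBD1, MELK and PLS3. Higher were GAB2, BAX, TPM2, KRT18, NCS1, ZSCAN18, IER2, POM121C and SGK1, a kinase induced by serum, which changed by 1.05. One other NUP50 probe set had the opposite sign. In all, 2 probe sets passed upward and 0 downward, with 1948 at an unadjusted p under 0.05. The count was 0 without EWS-FLI1 transient replicate 2 or EGFP transient replicate 2, and 1, FLI1, without any of wild type replicate 1, wild type replicate 2 or EGFP transient replicate 1. Without EWS-FLI1 transient replicate 1 there was 1, which was neither of these 2. It was 1590 without bulk and 52 without clone F. With all 5 arrays that lack EWS-FLI1 as the control, 189 passed upward and 623 downward.

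Across genes, the transient and the stable change were nearly unrelated, with Pearson's r of 0.041 and Spearman's rho of 0.048 over 9617 genes, which are not independent replicates. Signs matched for 51.5% of genes. At an unadjusted p under 0.05, 23 genes were higher in both modes, BAX, GAB2, KRT18, SGK1, TIMP2 and TPM2 among them, where 12.9 would overlap by chance (Fisher's exact test, two-sided p = 0.00827). Lower in both were 22, CA2, MELK and TP53BP1 among them, where chance gives 26.7 (Fisher's exact test, p = 0.406).

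The difference between the modes, stable minus transient, was tested as such. No gene passed: limma called 0 probe sets, with 1704 at an unadjusted p under 0.05 and a smallest adjusted p of 0.156, for the DHRS2 probe set 206463_s_at at 2.63. FLI1 differed by -3.70 on the log2 scale without passing (adjusted p = 0.317), though it passed without the bulk array; CXCL8, a chemokine, differed by -3.27, and THAP12, METTL5, PDCD10, STAG1, LYRM9, ZFR, RAI14 and FXR1 were also lower. Higher were BRD2, HMX1, DHRS2, HTR3A, GNL3L, SETMAR, ALDH9A1, ZSCAN18, MAGED1 and PDPK1, with adjusted p up to 0.381. Other probe sets of GNL3L and STAG1 had the opposite sign. The p53 targets (median -0.51) and the stress list (median 0.24) did not pass at an adjusted p of 0.0705 each. Without bulk 1533 probe sets passed, without clone F 2 and without EWS-FLI1 transient replicate 1 there was 1, and with bulk and clone F as separate groups there were 623 (95 up, 528 down).

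The EGFP vector alone, against wild type, gives the background of transfection. In transient cells DHRS2 (214079_at), a short-chain dehydrogenase, rose from 270 ± 130 to 1358 ± 27.7 (SD, n = 2 each), a log2 change of 2.23 (adjusted p = 0.025). The probe set 222227_at, for which no gene is listed, rose from 15.4 ± 10.6 to 3002 ± 682 (SD, n = 2 each), a log2 change of 5.70 (adjusted p = 2.77e-06) whose size depends on the added 43, since both wild-type values lay below it. It read 1395.2 and 1728.1 with transient EWS-FLI1, 687.5 with stable EGFP, 384.3 in bulk and 810.7 in clone F. TP53I3, a p53 target, rose adjusted over the list alone, from 15.8 ± 5.59 to 200 ± 6.08 (SD, n = 2 each), and no list passed (lowest adjusted p = 0.304, ribosomal proteins).

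Those 2 probe sets were the only ones called, 2 up and 0 down, with 794 at an unadjusted p under 0.05. Higher without passing were TP53I3, PDPK1, RPAIN, BRD2, COPA, EIF2S3, GNL3L, RBM48 and IGHG1, with adjusted p from 0.563 to 0.988. Lower without passing were SLC10A3, NUP210, CDC42BPA, KLF13, DPP3, ANO10, ASPSCR1, CCDC177, NRSN2 and PTPN1, with log2 changes from -0.96 to -2.05. Other probe sets of RPAIN, COPA, GNL3L, RBM48, NUP210 and CDC42BPA had the opposite sign. The count was 1 without wild type replicate 2, EGFP transient replicate 1 or EGFP transient replicate 2, and 8 without bulk or without clone F. DHRS2 missed the threshold without wild type replicate 2, either array of transient EGFP or either array of transient EWS-FLI1.

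The stable EGFP array, which carries vector and G418 selection but no EWS-FLI1, differed from wild type in many genes. SLC7A11, which imports cystine, fell from 2021 ± 218 (SD, n = 2) to 80.1, a log2 change of -4.06 (SE 0.29, adjusted p = 8.06e-05), and read 82.4 in bulk and 104.6 in clone F. It belongs to the list of unfolded protein and amino acid stress, which fell: 22 of 24 members were lower, with a median log2 change of -1.01 (camera adjusted p = 2.44e-14; adjusted p = 0.073 with an estimated correlation). Of these, 8 fell over all genes and 17 adjusted over the list alone, with log2 changes of -1.32 for the chaperone HSPA5, -1.46 for HERPUD1 and -1.28 for the transcription factor ATF3. Among named genes past the threshold the highest were the elongation factor EEF1A2, from 1156 ± 37.7 (SD, n = 2) to 5487.2, and the retinoic acid-binding protein CRABP2, from 296 ± 0.566 (SD, n = 2) to 1454.2. The probe set 222227_at, without a listed gene, rose more, to 687.5 (adjusted p = 0.00188).

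Genes of energy metabolism rose in the same array. For mitochondrial respiration, 29 of 32 members were higher, 5 rose over all genes and 17 adjusted over the list alone, with NDUFA1 up by 1.31 and SDHA by 1.01 on the log2 scale (adjusted p = 2.48e-13; adjusted p = 0.073 with an estimated correlation). For glycolysis and hypoxia, 20 of 25 were higher, 2 rose over all genes, ALDOA by 0.86 and PGAM1 by 0.79, and 4 adjusted over the list alone (adjusted p = 2.79e-06; adjusted p = 0.192 with an estimated correlation). All 30 ribosomal protein genes were higher, with 0 past the threshold over all genes and 14 adjusted over the list alone (adjusted p = 2.14e-13; adjusted p = 0.391 with an estimated correlation), but the list did not pass after quantile normalization (adjusted p = 0.293). On the stable arrays the GAPDH control, which takes no part in the tests, read 23485.7 in stable EGFP, 24889.7 in bulk and 25343.5 in clone F, and 15895.4 at most on the others. GAPDH is itself a gene of the glycolysis list. The ACTB control was also brighter, at 17500.8, 18845.9 and 19767.1 on these arrays and 15258.4 at most on the others. A brighter control was thus not particular to energy metabolism.

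In all, 93 probe sets passed upward and 60 downward, covering 72 and 34 genes, and after quantile normalization 79 and 82, with 110 shared. Also among the largest rises of named genes were FKBP8, SF3A2, UCP2, ASMTL, NME4, L1CAM, APOC1 and HSPB1, with log2 changes from 1.60 to 2.10, and among the largest falls ABCA11P, CCNP, ERO1B, TAOK1, KIAA0513, SND1-IT1, DAPP1, ZSCAN18 and RAPGEF2, from -1.68 to -2.56. Another probe set of RAPGEF2 had the opposite sign. The comparison rests on 1 array against 2: the count was 4 without wild type replicate 1 and 3 without wild type replicate 2. It was 8 without EWS-FLI1 transient replicate 1 or 2, 16 without EGFP transient replicate 1, 12 without EGFP transient replicate 2, 1687 without bulk and 1715 without clone F.

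Clone F and the bulk population, 1 array each, were compared by value only. CCL20, a chemokine, read 9.5 in bulk and 1993 in clone F. The metallothioneins MT1X and MT2A, which bind metal ions, read 562.3 and 1161.8 in bulk against 6143 and 7142.3 in clone F. PLK4, a kinase of centriole duplication, read 544.6 in bulk and 24.5 in clone F, and the lipid transfer protein PLTP 1056.2 and 103.4. Of 9617 genes, 361 were over 2-fold higher and 728 over 2-fold lower in the clone. BEX1, GALNT14, TRIM25, KANK1, PGBD5, HTR6 and IGFBP5 were also among the highest. LTBP4, SUCLA2, UTRN, SULF1, PIGV, LOXL1, ZC3H13 and DCLRE1A were among the lowest. Many probe sets also differed over 2-fold between replicate arrays. Of 16661 probe sets, 1949 did so between bulk and clone F. The counts were 942 for the wild-type pair, 1533 for transient EGFP and 974 for transient EWS-FLI1. The median of extracellular matrix and adhesion genes lay at the 0.84th percentile of random lists, that of the cell cycle at the 2.2nd and that of EWS-FLI1 activated targets at the 3.17th, while p53 targets lay at the 97.1st and the stress list at the 98th. With no replicate of either population, no difference between them was tested.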

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

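Of the tests given here, those of degraded RNA, of EWS-FLI1 in the selected cells and of splits inside each mode were chosen only after the result was seen, as were the comparison of the 3 G418-selected arrays with the other 6, the control transcripts read and the ratio above which they are listed.

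Control probe sets take no part in the comparisons. The GAPDH control read 1.60 times its wild-type mean on the stable EGFP array and 1.72 times that mean on the stable EWS-FLI1 arrays. The control for 28S ribosomal RNA read 2.61 times its wild-type mean on the stable EGFP array. Each ratio of the stable EGFP cells rests on 1 array.

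For the mean of both modes, the 7 transfected arrays were also split in every way into 4 and 3 and fitted with 2 groups. The real split of EWS-FLI1 from EGFP called 0 probe sets in that fit, so that 35 of 35 splits calling as many says nothing about chance. The highest other split called 4305 and parted the 3 G418-selected arrays from the 4 transient ones, which is a structure of the samples. The fit with a mean per group was therefore repeated for the 18 splits inside each mode, which are too few for a share under 0.05: 7, the real one with 2 calls included, called as many, and the highest other called 803, with the single array set apart among the G418-selected ones being clone F, again a structure of the samples.

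The 3 G418-selected arrays differed from the other 6 in 5570 probe sets. Of 84 splits into 3 and 6, 1 called as many, the real one, with 1 as the highest of the others. This argues against chance but does not exclude it, since the comparison was chosen only after the result was seen. The 3 arrays are also not replicates of 1 condition. The scaling of the arrays is argued against as the whole source, since 78.9% of the calls were made in the same direction after quantile normalization. More degraded RNA stays open: the log2 ratio of 3′ over 5′ control signal was -0.0936 relative to the others (SE 0.0647), with GAPDH at 0.09 and ACTB at -0.28. An effect of EWS-FLI1 stays open for part of it. Over the 5321 probe sets called between the stable EWS-FLI1 and the 4 transient arrays, the single stable EGFP array was set against wild type. It moved by 50.2% of the median EWS-FLI1 shift, with 91.9% of the probe sets in the same direction. The controls differ and the probe sets were chosen by the EWS-FLI1 shift, so 50.2% does not measure what EWS-FLI1 adds. G418 selection, time in culture and any handling shared by these 3 arrays cannot be told apart, since the labels give no batch.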

How the results depend on the processing

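Bulk and clone F as separate groups, the lists with wild type as control or without each array, the list test of the difference, and the G418 comparison were chosen after seeing the data. Signal over background limits dim genes. Except where a construction is named, the cause was not tested. By construction, bulk and clone F enter the transient comparison and those of EGFP against wild type only through the pooled spread. Setting them apart or leaving either out therefore keeps the log2 changes of these comparisons and moves their counts through that spread. The direction of the FLI1 change in transient cells, in stable cells, over both modes and in their difference held in all alternatives run for it.

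Transient calls (1) became 3 after quantile normalization, 3 with an added constant of 162, 20 with only the groups compared, 28 with bulk and clone F apart and 2 against wild type. Stable calls (0) became 1325 with bulk and clone F apart, where their difference leaves the pooled spread, and 4185 against wild type. Calls over both modes (2) became 1 with only the groups compared, 843 with bulk and clone F apart, 1 with a replicate term and 812 with all 5 arrays without EWS-FLI1 as control. The difference (0) gave 1 with 162 added and 623 with bulk and clone F apart. For transient EGFP (2), calls were 1 with 10.75 added, 1 without a filter, 9 with only the groups compared, 8 with bulk and clone F apart and 1 with a replicate term. For stable EGFP (153), they were 85, 19, 2730 and 1611 under the first 4 of these. With the replicate term the transient count stayed 1 and the difference 0.

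Leaving out each array in turn gave 0 to 28 calls for transient, 0 to 2136 for stable, 0 to 1590 for both modes, 0 to 1533 for the difference, 1 to 8 for transient EGFP, 3 to 1715 for stable EGFP and 4332 to 5806 for the G418 comparison. Lists passing ranged from 1 to 4 for transient, 0 to 1 for stable, 0 to 4 for both modes, 0 to 2 for the difference, 0 to 1 for transient EGFP and 4 to 5 for stable EGFP. The correlation between modes ranged from 0.00344 to 0.0696, and it was 0.0873 with the filter at the 50th percentile.

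With an estimated correlation 0 lists passed in the transient, stable and both-mode comparisons and for stable EGFP. Transient lists (1) were 2 after quantile normalization, with the filter at the 50th percentile and with the mean of a gene's probe sets, the immediate early genes being the second. Stable lists (1) were 5 against wild type. Lists over both modes (1) were 0 after quantile normalization, 2 without a filter, 3 with the filter at the 50th percentile, 2 with the mean of probe sets, 3 with bulk and clone F apart and 4 with all 5 arrays as control. The list of unfolded protein and amino acid stress was not among the 4 that passed with all 5 arrays as control.

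Against wild type, 8 named changes turned. In transient cells these were SLC10A3 to -0.00825 and DHRS2 to 0.67. In stable cells they were ZSCAN18 to -0.19, KIAA0513 to -0.0697, DAPP1 to -0.23, L1CAM to 0.51, DDIT3 to -0.21 and DDIT4 to -0.50. By construction, a sign turns only where EGFP and wild type differ in signal, so these 8 changes rest on the EGFP arrays. The other named changes of the transient and stable comparisons kept their direction against wild type. Wild type alone was not used as control for the mean of both modes. A change that keeps its direction can still rest largely on the EGFP arrays. EIF4G1 (208624_s_at) read 956 on average with EGFP, 1842 in wild type, and 2181 and 2095 with transient and stable EWS-FLI1. Without 1 array, EWSR1 (210012_s_at) in transient cells ranged from -0.20 to 0.37. The named changes followed here are FLI1, EWSR1 in transient cells, EIF4G1 over both modes, 222227_at, the genes with the largest or clearest change, members of lists that passed or of the EWS-FLI1 lists, and the named members that passed adjusted over their list alone. Of their other values over all settings, 515 kept their side of the threshold, 52 passed newly and 2 were lost for transient; 546, 117 and 0 for stable; 519, 98 and 11 for both modes; 437, 56 and 0 for the difference; 446, 0 and 8 for transient EGFP; and 535, 88 and 227 for stable EGFP, in the same direction as in the main comparison.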

Other observations

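The comparison of the 3 G418-selected arrays with the other 6 was chosen only after the result was seen, as were the tests of an endogenous response and of chance without FLI1 for 222227_at and, for p53 targets, those of transfection itself and of members that vary together.

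The G418-selected cells, 2 arrays with EWS-FLI1 and 1 with EGFP, differed from the other 6 arrays in many genes. SLC7A11, which imports cystine, fell to 89.0 ± 13.5 (SD, n = 3) from 1858 ± 310 (SD, n = 6), a log2 change of -3.84. The endoplasmic reticulum chaperone HSP90B1 fell to 787 ± 523 (SD, n = 3) from 2877 ± 377 (SD, n = 6). CRABP2 rose to 1573 ± 215 from 291 ± 57.0, EEF1A2 to 4921 ± 923 from 1124 ± 109, and the small heat shock protein HSPB1 to 2695 ± 361 from 739 ± 123 (SD, n = 3 and 6). The transcription factor SOX9 rose to 1260 ± 1162 from 217 ± 33.6 (SD, n = 3 and 6). In all, 2124 probe sets passed upward and 3446 downward, and 2443 and 2702 after quantile normalization.

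For the gene lists, members are counted as up or down here only if they passed over all probe sets. Of the 16661 probe sets tested, 5570 passed in either direction. Mitochondrial respiration rose, with 24 of 32 members up (camera adjusted p = 3.63e-11, and 0.0178 with an estimated correlation). Unfolded protein and amino acid stress fell, with 16 of 24 members down (adjusted p = 7.95e-07; adjusted p = 0.0935 with an estimated correlation). Glycolysis and hypoxia rose, with 12 of 25 members up (adjusted p = 2.27e-06; adjusted p = 0.065 with an estimated correlation), as did EWS-FLI1 repressed targets, with 10 of 30 up (adjusted p = 0.00815; adjusted p = 0.0935 with an estimated correlation). Ribosomal proteins rose with 20 of 30 up (adjusted p = 6.42e-09; adjusted p = 0.406 with an estimated correlation), but the list did not pass after quantile normalization (adjusted p = 0.725). The cell cycle list had 12 members up and 11 down and did not pass (adjusted p = 0.678).

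The p53 targets were higher on the transient EWS-FLI1 arrays than with EGFP. Relative to wild type the list's median was 0.21 and 0.47 on the EWS-FLI1 arrays. On the EGFP arrays, which were transfected too, it was 0.01 and -0.07, with 8 of 17 members above wild type on average. For the list's median only, this argues against transfection shared by both groups. The difference of means, 0.37 (SE 0.14 between arrays, n = 2 each), is the pattern itself and no separate test of its cause. The member TP53I3 rose with EGFP alone, by 2.07 and 2.02, against 2.38 and 1.81 with EWS-FLI1. A transfection of unequal strength was not tested. Members that vary together stay open, since the adjusted p was 0.631 with an estimated correlation of 0.20. The 15 splits of the 6 transient and wild-type arrays into 2 and 4 are too few for a share under 0.05: 1 split gave as small a p, the real one at 1.02e-10, with 8.09e-04 as the next.

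The probe set 222227_at was bright on all 7 transfected arrays and dim in wild type. The planned test did not exclude chance among dim probe sets: of the 36 choices of 2 arrays, 2, a share over 0.05, had a probe set that parted them from the rest by as large a ratio, wild type at 6.48 and the transient EWS-FLI1 pair at 10.7 through FLI1, the introduced gene. Without the FLI1 probe sets 1 of 36 did, wild type, and the next reached 3.72, which argues against chance only in this test chosen afterwards. A response of an endogenous gene to transfection stays open: the 1 probe set over 4-fold higher on every transfected array than in wild type was 222227_at itself, which decides nothing, since a single gene can respond. Whether it reads a sequence of the vector was not tested.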
